A study of Mus musculus with 4 samples.

How the data were processed

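Cultured primary mouse hepatocytes were sampled at 4 stages of a protocol that aims at insulin-producing cells, and total RNA of each stage was sequenced as 1 library. Per the labels' protocols, cells were first grown in high-glucose medium with 10% fetal bovine serum. Stage S0 was the serum-free medium with knockout serum, basic fibroblast growth factor and epidermal growth factor, both at 20 ng/ml. For stage S1 the DNA methylation inhibitor 5-azacytidine was given for 48 h, at a dose labelled as 5 mM, followed by the histone deacetylase inhibitor trichostatin A at 100 nM for 24 h. Stage S2 followed 7 days of insulin, transferrin and selenium supplement with retinoic acid, at a dose labelled as 2 mM. Stage S3 followed 7 days of nicotinamide at 10 mM in medium without both growth factors. Both millimolar doses of 5-azacytidine and retinoic acid are given as the labels print them, and the unit was not checked against another source.

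Per the labels' protocols, RNA was isolated with Trizol and libraries were made with a stranded total RNA kit and sequenced on an Illumina machine. Per the submitters' processing notes, the genome build was mm9 and bcl2fastq was among the tools used, with no version. The aligner, the counting program, the annotation release and whether counting used the strand are not given in the sources used here. Reads of genes that overlap on opposite strands, and of close paralogs (the Serpina1, Serpina3, Gsta, Gstm, Ugt2b, Cyp2, Cyp3a, Cyp4a and Ces families among the genes named), are therefore uncertain where the counting could split or share them.

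The authors deposited a table of read counts per gene and a table of RPKM values per gene (read counts scaled by gene length and library size), each named as such per the file headers. The counts were whole numbers whose sums differed between libraries. Both tables cover the same 30138 entries, each with a gene identifier, symbol, chromosome and biotype and without start or end coordinates, so none are printed. Of these, 6520 had 0 reads in all 4 libraries, 715 were unannotated long non-coding transcripts with assembly names, and 45 shared their gene symbol with another entry. Gene symbols and identifiers are those of the tables. For each gene the ratio of the deposited count to the deposited RPKM was the same between libraries up to 1 factor per library, which relative to S0 was 0.966 for S1, 0.828 for S2 and 0.866 for S3 over genes with at least 200 reads. The corresponding ratios of reads in genes were 0.966, 0.831 and 0.856. The RPKM table thus rests on the same reads as the count table, and the counts were used for every reported value.

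Reads in genes numbered 27602967 in S0, 26655887 in S1, 22944047 in S2 and 23633176 in S3. Counts were scaled to CPM, the usual unit of counts relative to library size, with TMM factors from edgeR 4.0.16 in R 4.3.3, computed over all 4 libraries (0.968, 1.089, 0.957 and 0.991). Genes with at least 1 CPM in at least 1 library were kept, which left 15222 genes, of which 14032 were protein-coding, 1186 long non-coding (322 of them unannotated) and 4 immunoglobulin or T cell receptor segments. For each gene and comparison the log2 ratio of scaled CPM was computed with an exact 95% Clopper-Pearson interval on the share of the reads of both libraries. A gene was counted as higher or lower when its whole interval lay beyond 2-fold. A gene that reached 1 CPM in only 1 library has its highest value there, so its direction against that library is fixed by the filter. A gene with 0 reads in a library was set against a floor of 3 reads in that library (0.112, 0.103, 0.137 and 0.128 CPM in S0 to S3), which gives a lower bound, written as "at least". No ratio was given when both libraries had 3 reads or fewer. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

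With 1 library per stage there is no estimate of the spread between cultures, so no p-value was computed across genes and no difference has a replicate check. Intervals and floors cover counting error only, and reads that were amplified without molecular identifiers are not independent molecules. The 4 comparisons were S1 over S0, S2 over S1, S3 over S2 and S3 over S0. All 4 libraries entered the scaling, and no library was left out.

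Before the data were examined, 37 gene lists, the rule for the genes named and 8 processing alternatives were fixed. The lists cover hepatocyte, biliary, pancreatic, neural and germline genes, markers of other cells that a liver preparation can hold, and pathways the medium additions act on. For each list the median log2 ratio of its measured members was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries and is not a test of the conditions. Members at 0 reads entered the median at their bound. Named genes were, per comparison, the 12 higher and 12 lower genes whose interval bound nearest to no change lay farthest out (without predicted or clone names, pseudogenes and small RNAs), up to 6 members of each list, and 20 genes fixed by name. Genes named outside that rule are marked as chosen after their values were seen.

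The steps were tested on simulated counts with 200 changed genes. Of genes changed 4-fold, 93.0% were recovered in the simulation of S1 over S0 (14435 genes), 95.0% of S2 over S1 (14417 genes), 91.0% of S3 over S2 (14434 genes) and 99.0% of S3 over S0 (14400 genes). Of genes changed 3-fold, 87.0%, 88.0%, 86.0% and 87.0% were recovered in the same order. No unchanged gene was called in any of the 4 simulations (0 of 14235, 14217, 14234 and 14201). With counting error alone such calls are hardly possible, so this says nothing of false calls from differences between cultures. A list of genes all raised 4-fold lay at percentile 100.0 in each simulation, which its construction all but fixed. A list of unchanged genes lay at 14.3, 62.9, 54.2 and 2.3, so a list without change can reach the outer percentiles. Intervals covered the true ratio for 95.4%, 95.5%, 95.2% and 95.4% of genes. In the data 3904 genes lay beyond 2-fold in S1 over S0, against 200 changed genes here. The scaling and recovery were therefore not tested under so broad a change.

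The alternatives were CPM without TMM, DESeq2 1.42.0 size factors, no filter on low counts, a minimum of 10 CPM, an interval beyond 4-fold, a point estimate beyond 2-fold, and the deposited RPKM values at 2-fold with a pseudocount of 1 or 0.1. Small RNAs were not analysed here, so nothing is said of the microRNA that the series title names.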

Results

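RNA of primary mouse hepatocytes was sequenced at 4 stages of stepwise culture toward insulin-producing cells, with 1 library per stage. S0 was the serum-free starting culture, S1 followed 5-azacytidine and trichostatin A, S2 followed retinoic acid with insulin, transferrin and selenium, and S3 followed nicotinamide without growth factors. The series asks how messenger and long non-coding RNAs differ between the stages, and its title names the long non-coding RNA Malat1, a microRNA and phosphoinositide 3-kinase (PI3K) signalling. Reads in genes ranged from 22944047 (S2) to 27602967 (S0), so a gene with 0 reads lay below 0.103 to 0.137 CPM. Values in parentheses after a fold are its 95% counting interval (Clopper-Pearson), which covers counting error only. Since each stage is a single library, a difference between stages has no replicate check and cannot be separated from a difference between cultures or libraries.

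Protein-coding genes held 99.03%, 97.3%, 97.55% and 98.33% of the reads of S0 to S3, and long non-coding RNAs 0.97%, 2.7%, 2.45% and 1.67%. The most abundant transcript was Actb in S0 (1.14% of reads), Malat1 in S1 (1.96%) and S2 (1.71%), and the mitochondrial mt-Co1 in S3 (2.51%). Macrophage transcripts were abundant in the starting culture. Lyz2, the macrophage lysozyme, chosen after its values were seen, took 0.865% of the reads in S0, 0.265% in S1 and 0.052% in both S2 and S3, while Alb, the hepatocyte product albumin, took 0.023%, 0.188%, 0.686% and 0.354%.

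**Figure D1:**
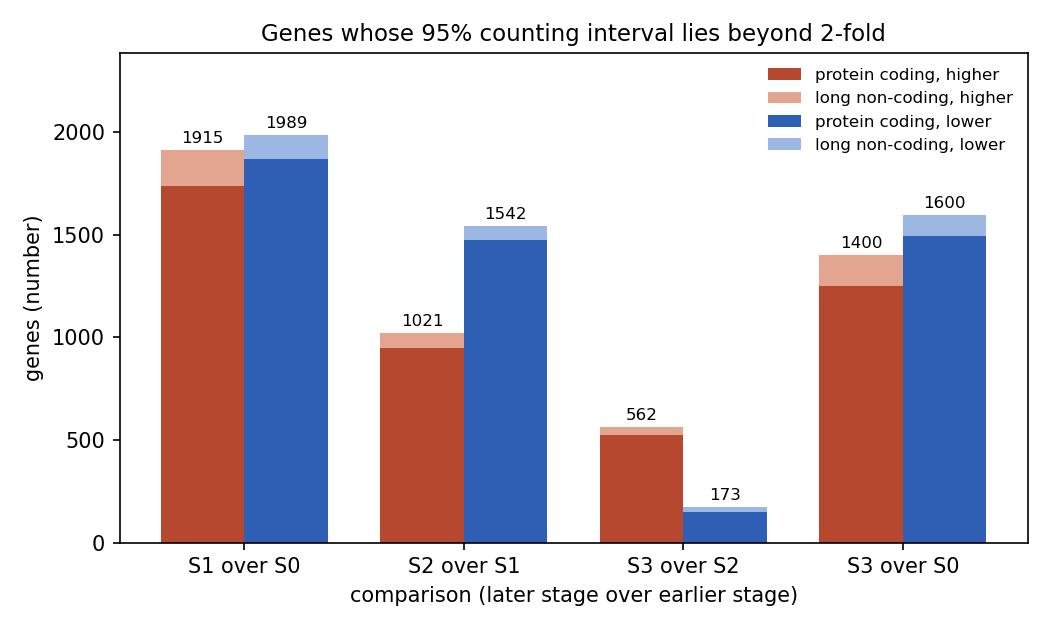
Number of genes whose 95% counting interval lay beyond 2-fold in each of the 4 comparisons (x axis; later stage over earlier stage), split into protein-coding and long non-coding genes, higher (red) and lower (blue). The numbers above the bars count all genes, including T cell receptor segments that the bars leave out, and read 1915 and 1989 for S1 over S0 and 562 and 173 for S3 over S2.

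The first comparison, S1 over S0, covers the step with the inhibitors of DNA methylation and histone deacetylation. Malat1 (ENSMUSG00000092341), a nuclear long non-coding RNA on chromosome 19, stood at 4602 CPM in S0 and 18013 CPM in S1, a 3.91-fold difference (3.89 to 3.94). Neuronal and secretory granule genes were higher in S1, with the neurofilament gene Nefl 185-fold higher (72.0 to 681) and the granule protein gene Chga, with 0 reads in S0 and 256 in S1, at least 78.5-fold higher. Macrophage genes and cell cycle genes were lower, with the colony-stimulating factor receptor gene Csf1r 19.3-fold lower (18.2 to 20.4) and the proliferation marker Mki67 15.7-fold lower (14.7 to 16.7). In total 1915 genes were higher in S1 and 1989 lower, which is 12.6% and 13.1% of the 15222 genes tested.

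Of 22 listed neural markers, 14 were measured, and 11 of these were higher in S1 and 0 lower. Their median was 10.1-fold higher, above all 10000 random lists (percentile 100.0). Syp, Syt1 and Gap43 reached 1 CPM in S1 alone, so they could only be higher in S1. The filter thus fixed in part the count of 0 lower and the percentile. The synaptic vesicle gene Syt1 was 68.1-fold higher (26.3 to 251), Elavl3 73.0-fold (24.7 to 356) and the dendritic protein gene Map2 20.0-fold (16.5 to 24.5). The farthest higher genes by the fixed rule included further genes known from neurons, among them Amph (310-fold, 55.3 to 12300, with 1 read in S0), Mapk8ip2 (at least 169-fold), Cbln1 (at least 64.7-fold) and Grid1 (at least 63.2-fold). Dtx1, a Notch pathway gene with 2 reads in S0 and 881 in S1, was 405-fold higher (112 to 3350).

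Of 25 listed islet hormone and secretory granule genes, 11 were measured, and 9 of these were higher and 0 lower. Their median lay at the bound of Scg2, at least 10.1-fold higher (percentile 100.0). The median of their S0 levels was 0.487 CPM, below the limit of 1 CPM. Many were therefore measured only through a later stage, which favours higher calls. Vgf was 38.1-fold higher (30.5 to 48.2), Scg5 18.3-fold (10.5 to 34.8) and Pcsk1n, with 0 reads in S0 and 101 in S1, at least 31.0-fold. The insulin gene Ins1 and the endocrine progenitor factor gene Neurog3 had 0 reads at all 4 stages, and Ins2 had 0 reads in S0, S1 and S2 and 1 read in S3. Of 24 listed pancreatic transcription factors, 11 were measured, with 4 higher and 2 lower (median 1.77-fold higher, percentile 89.0). The 4 were Pax6 (24.2-fold, 7.99 to 120), Mafa (14.7-fold, 5.48 to 55.7), Mnx1 (at least 17.8-fold) and Pou3f4 (4.06-fold, 2.14 to 8.35), and among the lower ones was St18 (46.6-fold, 21.1 to 128). In S1 Mafa stood at 2.2 CPM and Pdx1 at 0.689 CPM (20 reads, against 6 in S0). Of 15 beta cell genes for glucose sensing and secretion, 5 were higher and 2 lower (median 1.47-fold higher, percentile 84.0), the higher ones including Snap25, a protein of synaptic and granule fusion (105-fold, 40.7 to 387), and Abcc8, a subunit of the beta cell potassium channel (5.06-fold, 2.36 to 12.4).

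Macrophage and Kupffer cell markers were lower for 21 of 26 members and higher for 3, with a median 4.94-fold lower (percentile 0.0). The scavenger receptor gene Msr1 was 90.2-fold lower (82.2 to 99.1), Mrc1 20.7-fold (19.5 to 21.9) and the neutrophil and macrophage oxidase gene Ncf1 186-fold (132 to 272). The 3 higher members were Marco (2.3-fold, 2.19 to 2.43) and, chosen after their values were seen, Cd5l and H2-Ab1. Gene groups with many leukocyte genes held lower members beside them. Inflammation genes had 12 of 23 members lower and 1 higher (median 2.34-fold lower, percentile 0.0), with Tnf 29.1-fold lower (21.1 to 41.1), and interferon response genes had 10 of 26 lower and 1 higher (median 2.19-fold lower, percentile 0.0). Of the 42 measured PI3K-AKT pathway genes, 8 were lower and 1 higher. The median was 1.06-fold lower (percentile 53.1) and turned to higher without TMM scaling. Those farthest down were the leukocyte subunits Pik3cg (20.5-fold, 16.9 to 25.1) and Pik3cd (8.42-fold, 7.38 to 9.63) and the leukocyte phosphatase gene Inpp5d (16.6-fold, 14.9 to 18.6), and the 1 higher was Foxo1 (2.37-fold, 2.05 to 2.74), chosen after its values were seen. The widely expressed subunits did not pass the 2-fold rule, with ratios of 1.1-fold lower for Pik3ca (1.05 to 1.16), 1.35-fold higher for Pik3cb (1.26 to 1.45) and 1.44-fold lower for Pik3r1 (1.36 to 1.51), nor did Akt1 (1.71-fold lower, 1.65 to 1.78).

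Cell cycle genes were lower for 32 of 34 members and higher for 0, with a median 5.98-fold lower (percentile 0.0). Top2a was 9.55-fold lower (8.98 to 10.2) and the mitotic kinase gene Plk1 10.9-fold (8.9 to 13.5). Of 29 DNA methylation and histone deacetylation enzymes, the families the step inhibits, 10 were lower and 2 higher (median 1.55-fold lower, percentile 0.2). Dnmt1, the maintenance methyltransferase, was 2.9-fold lower (2.77 to 3.05), its partner Uhrf1 6.99-fold (6.39 to 7.67) and Hdac9 10.2-fold (7.57 to 14.1), while Hdac11 was 2.85-fold higher (2.3 to 3.54). Of 35 listed germline genes that are methylated in somatic cells, only 8 reached 1 CPM in at least 1 library and were measured. Of these 8, 3 were higher and 0 lower (median 2.6-fold higher, percentile 93.0): Tex15 (12.5-fold, 9.58 to 16.6), Brdt (5.94-fold, 3.29 to 11.6) and Tdrkh (3.44-fold, 2.75 to 4.33).

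Hepatocyte genes differed in both directions. Of 40 listed plasma protein genes, 32 were measured, with 15 higher and 5 lower (median 2.33-fold higher, percentile 100.0). Apoa1 was 32.5-fold higher (27.8 to 38.1), Alb 7.38-fold higher (7.18 to 7.57) and Vtn, with 3 reads in S1, 16.7-fold lower (5.36 to 83.8). Of 24 liver transcription factors, 6 were lower and 3 higher (median 1.17-fold lower, percentile 19.3), and Hnf4a, a central hepatocyte factor, was 2.77-fold lower (2.58 to 2.97). Of 42 listed hepatocyte enzymes and transporters, 21 were measured, and the others stayed below 1 CPM at every stage. Of the 21 measured, 3 were higher and 1 lower (median 1.15-fold higher, percentile 73.9). The lower one was the urea cycle gene Arg1 (67.7-fold, 46.9 to 101), which macrophages also express. Oxidative stress genes of the NRF2 pathway were higher for 12 of 26 members and lower for 0 (median 1.69-fold higher, percentile 100.0), including the quinone reductase gene Nqo1 (20.0-fold, 18.5 to 21.8). Cholesterol synthesis genes had 6 of 23 members higher and 0 lower (median 1.53-fold higher, percentile 100.0), and fatty acid synthesis genes 6 of 19 higher and 2 lower (median 1.69-fold higher, percentile 100.0).

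Epithelial-mesenchymal transition genes had 9 of 25 members lower and 0 higher (median 1.7-fold lower, percentile 0.0), including Tgfbi (35.5-fold, 30.5 to 41.6), a gene macrophages also express, and the contractile gene Cnn1 (7.81-fold, 7.35 to 8.31). Stellate cell and fibroblast markers went both ways, 6 of 32 higher and 6 lower (percentile 43.0), and among the lower ones was Acta2, the smooth muscle actin (7.29-fold, 7.17 to 7.41). Biliary and progenitor markers had 7 of 22 members higher, Epcam among them (10.1-fold, 8.26 to 12.4), and 4 lower, Krt19 among them (2.36-fold, 2.26 to 2.47), with percentile 73.6. Of 29 named long non-coding RNAs, 6 were higher and 3 lower, and their median was 1.4-fold lower (percentile 2.0). Neat1, which lies on the same chromosome as Malat1, was 3.02-fold higher (2.95 to 3.09) and Miat, with 0 reads in S0, at least 56.1-fold higher, while H19 was 5.75-fold lower (4.37 to 7.67). Long non-coding genes made up 176 of the higher and 116 of the lower genes, and 97 and 18 of these were unannotated. Without TMM scaling the median of all genes tested moved by 0.17 on the log2 scale, and the numbers of higher and lower genes were 2321 and 1631.

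The second comparison, S2 over S1, covers the retinoic acid step. In S2, 18 of 32 plasma protein genes, 10 of 24 liver transcription factors and 12 of 26 retinoic acid response genes were higher, while most neural and macrophage markers and 5 of 11 granule genes were lower. Cyp26a1, the retinoic acid-degrading enzyme, had 1 read in S1 and 320 in S2 (423-fold higher, 75.4 to 16800), and Alb was 4.16-fold higher (4.12 to 4.2), reaching 7171 CPM. Malat1 differed little, at 17866 CPM in S2 (1.01-fold lower, 1.0 to 1.01). In total 1021 genes were higher and 1542 lower, so 39.8% of these genes were higher. That share was 27.1% without TMM scaling (711 higher and 1911 lower), which moved the median of all genes by -0.19 on the log2 scale.

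Retinoic acid response genes had 12 of 26 members higher and 3 lower (median 2.67-fold higher, percentile 100.0). In S1 over S0, before retinoic acid was given, this list had 6 members higher and 3 lower (median 1.47-fold higher, percentile 98.0). Dhrs3, a retinaldehyde reductase, was 19.5-fold higher (17.7 to 21.6), Cyp26b1 11.3-fold (8.89 to 14.6) and Hoxa5 7.36-fold (6.26 to 8.69). The 3 lower members were Crabp1 (at least 32.5-fold) and the retinoic acid-producing enzymes Aldh1a3 (12.1-fold, 7.89 to 19.6) and Aldh1a2 (10.7-fold, 7.69 to 15.3). These 3 had been higher in S1 than S0, with log2 ratios of 3.57, 4.64 and 2.57 in the same order. Dhrs3 had been lower in S1 than S0 (log2 ratio -2.59).

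Of 24 liver transcription factors, 10 were higher and 0 lower (median 2.15-fold higher, percentile 100.0), with Hnf4a 6.02-fold higher (5.64 to 6.43) and the bile acid receptor gene Nr1h4 5.58-fold (4.43 to 7.11). Plasma protein genes had 18 of 32 members higher and 2 lower (median 2.62-fold higher, percentile 100.0), including Ttr (12-fold, 11.2 to 12.9), Plg (at least 19.4-fold) and Vtn (54.6-fold, 18.3 to 269). Enzymes and transporters had 5 of 21 higher and 2 lower (median 1.65-fold higher, percentile 99.9), with the canalicular transporter gene Abcc2 16.2-fold higher (15.2 to 17.2). Outside the lists, Acox2, an enzyme of bile acid synthesis, was 25.3-fold higher (20.4 to 31.7) and Cyp2a5 30.7-fold (18.3 to 55.4). The fetal liver gene Afp was 2.77-fold higher (2.74 to 2.79). NRF2 pathway genes had 9 of 26 higher and 0 lower (median 1.62-fold higher, percentile 100.0), cholesterol synthesis genes had 3 of 23 higher and 0 lower (median 1.72-fold higher, percentile 100.0), and fatty acid synthesis genes had 4 of 19 higher and 3 lower (median 1.45-fold higher, percentile 98.6). Mitochondrially encoded genes had 2 of 13 members higher, mt-Nd4 and mt-Nd5, and 0 lower (median 1.88-fold higher, percentile 100.0).

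Neural markers were lower for 10 of 14 members and higher for 0 (median 6.55-fold lower, percentile 0.0), with Syt1 37.3-fold lower (16.9 to 102) and Map2 25.9-fold (20.4 to 33.3). Members that reached 1 CPM in S1 alone, such as Syt1, could only be lower in S2, so the filter fixed part of this result. Granule genes had 5 of 11 lower and 0 higher (median 1.75-fold lower, percentile 6.5), including Chga (38.7-fold, 16.4 to 120) and Vgf (4.45-fold, 4.07 to 4.88). Of the pancreatic transcription factors 3 of 11 were lower and 0 higher (median 1.53-fold lower, percentile 16.7), among them Mafa (4.03-fold, 2.16 to 8.21) and Mnx1 (at least 14.6-fold). Beta cell genes had 4 of 15 lower and 0 higher (median 1.7-fold lower, percentile 7.3), with Snap25 115-fold lower (39.1 to 560). Of 25 listed pluripotency and early endoderm genes, 9 were measured, with 5 lower and 0 higher (median 2.53-fold lower, percentile 1.0). Among the lower ones were Esrrb (13.9-fold, 4.5 to 69.3) and Lin28b (4.01-fold, 2.02 to 8.84). Of the 1915 genes higher in S1 than in S0, 854 were lower again in S2 than in S1 (44.6%), and of the 1989 lower in S1, 339 were higher again in S2 (17.0%). Both comparisons use the S1 library and are not independent, so how much of either overlap that single culture supplies is not known.

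Macrophage markers were lower once more, for 19 of 26 members with 1 higher (median 4.44-fold lower, percentile 0.0). Marco was 30.2-fold lower (25.3 to 36.5), the Kupffer cell marker Adgre1 16.4-fold (14.2 to 19.1) and the complement gene C1qc 16.3-fold (13.3 to 20.2), while Cd14 was 5.66-fold higher (4.7 to 6.86). Inflammation genes, 10 of 23 lower and 1 higher (median 1.55-fold lower, percentile 0.2), and interferon genes, 8 of 26 lower and 0 higher (median 1.75-fold lower, percentile 0.3), went with them, and the acute phase gene Saa3 was 52.5-fold lower (31.1 to 96.3). Cell cycle genes had 9 of 34 lower and 1 higher (median 1.75-fold lower, percentile 0.0), the higher one being Ccnd1, chosen after its values were seen, and the glycolysis list had 2 of 28 members higher and 2 lower (median 1.17-fold lower, percentile 0.2). Fibroblast markers went both ways, 7 of 32 higher, such as Dcn (4.82-fold, 4.47 to 5.2), and 9 lower, such as Thy1 (12.1-fold, 9.77 to 15.1), with a median 1.17-fold lower (percentile 0.8). Among 42 PI3K-AKT genes 1 was higher and 2 lower (percentile 32.5).

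**Figure D2:**
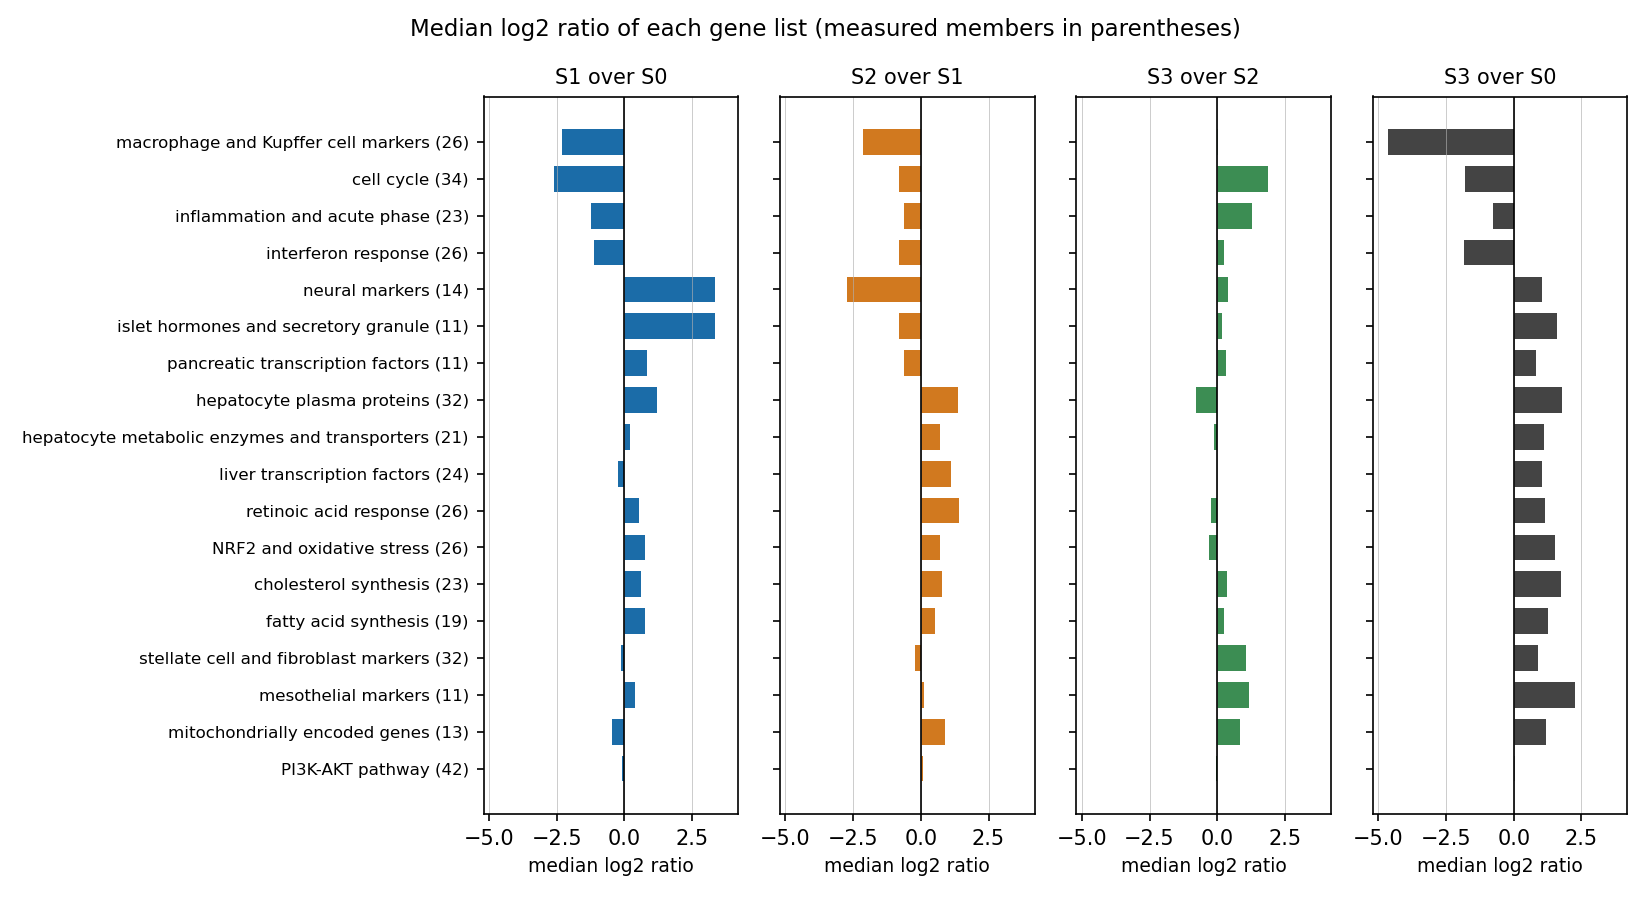
Median log2 ratio (x axis) of the measured members of 18 gene lists (y axis, number of members in parentheses) in the 4 comparisons. Macrophage markers lie at -2.31 and -2.15 in the first steps and near 0 in S3 over S2, while cell cycle genes lie at -2.58 in S1 over S0 and at 1.86 in S3 over S2. Without TMM scaling or with DESeq2 size factors, bars near 0 changed side for the fibroblast and PI3K-AKT lists in S1 over S0, the mesothelial and PI3K-AKT lists in S2 over S1, the liver transcription factors in S3 over S2 and the PI3K-AKT list in S3 over S0.

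The third comparison, S3 over S2, covers the nicotinamide step without growth factors and held the fewest genes beyond 2-fold, 562 higher and 173 lower. Many cell cycle, acute phase and mesothelial genes were higher in S3, and several plasma protein genes were lower. Mki67 was 6.54-fold higher (5.72 to 7.51), the collagen gene Col3a1 5.39-fold (5.2 to 5.58) and Saa3, with 14 reads in S2 and 3034 in S3, 203-fold (121 to 372). Apoa1 was 7.81-fold lower (7.29 to 8.36), and Malat1 was 2.14-fold lower (2.13 to 2.15), at 8340 CPM in S3. Slc2a2, the glucose transporter of hepatocytes and mouse beta cells, had 34 reads in S2 and 228 in S3 (6.29-fold higher, 4.37 to 9.3).

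Of the 34 cell cycle genes, 24 were higher and 0 lower (median 3.64-fold higher, percentile 100.0), with Plk1 10.8-fold higher (6.58 to 18.9) and Top2a 5.96-fold (5.34 to 6.67). Of the 23 p53 targets and cell cycle inhibitors, 4 were higher and 0 lower (median 1.45-fold higher, percentile 100.0), including the stress cytokine gene Gdf15 (6.25-fold, 5.37 to 7.31) and Trp53inp1 (2.37-fold, 2.31 to 2.42). Inflammation and acute phase genes were higher for 11 of 23 members and lower for 0 (median 2.4-fold higher, percentile 100.0), with the iron-binding protein gene Lcn2 36.4-fold higher (21.9 to 65.5) and the chemokine gene Ccl2 3.64-fold (3.28 to 4.06). The complement gene C3 was 10.7-fold higher (10.2 to 11.3). Macrophage markers had 0 of 26 members higher and 0 lower (median 1.03-fold higher, percentile 79.5).

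Stellate cell and fibroblast markers were higher for 11 of 32 members and lower for 0 (median 2.09-fold higher, percentile 100.0), including Col6a2 (12.9-fold, 10.3 to 16.4), Col6a1 (10.4-fold, 9.46 to 11.4) and Dcn (3.59-fold, 3.46 to 3.74), whereas Col1a1 did not pass the rule (1.16-fold lower, 1.14 to 1.19). Mesothelial markers were higher for 7 of 11 members and lower for 1 (median 2.26-fold higher, percentile 100.0), with Gpm6a 4.62-fold higher (4.4 to 4.86), Bnc1 2.7-fold (2.51 to 2.91) and Upk3b 2.26-fold (2.15 to 2.37), and Msln 2.8-fold lower (2.74 to 2.86). The Wnt pathway agonist gene Rspo1 was 16.7-fold higher (12.1 to 23.8), and the cell adhesion gene Cntn2 17.3-fold (16.1 to 18.7). Matrix proteases and inhibitors had 6 of 23 members higher and 1 lower (median 1.18-fold higher, percentile 99.8), with Mmp3 12.4-fold higher (6.31 to 27.8). Biliary and progenitor markers had 6 of 22 higher and 0 lower (median 1.48-fold higher, percentile 100.0), among them Cldn6 (9.67-fold, 7.51 to 12.7) and Krt7 (2.92-fold, 2.76 to 3.09).

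Plasma protein genes were lower for 11 of 32 members and higher for 5 (median 1.72-fold lower, percentile 0.0). Ttr was 2.41-fold lower (2.31 to 2.5) and Serpina1b 8.92-fold (8.48 to 9.38), while Gc, the vitamin D-binding protein gene, was 2.1-fold higher (2.06 to 2.13), and Alb was 2.01-fold lower with an interval that reached within the 2-fold rule (1.99 to 2.03). Enzymes and transporters had 4 of 21 members higher and 3 lower (median 1.09-fold lower, percentile 15.5), with the alcohol dehydrogenase gene Adh1 8.53-fold lower (5.86 to 12.8). Of 24 liver transcription factors 0 were higher and 0 lower (percentile 43.2), and Hnf4a was 1.43-fold lower (1.37 to 1.5). Retinoic acid response genes had 3 of 26 lower and 0 higher (median 1.17-fold lower, percentile 1.2), including Cyp26a1 (7.11-fold, 5.24 to 9.84). NRF2 pathway genes had 0 members beyond 2-fold and a median 1.24-fold lower (percentile 0.0), and no PI3K-AKT gene of 42 passed the rule (0 higher, 0 lower, percentile 19.2). The nicotinamide and NAD metabolism list had 3 of 24 members higher, Cd38, Bst1 and Qprt, and 0 lower (median 1.05-fold higher, percentile 70.2). Of 11 granule genes 1 was higher and 0 lower (median 1.14-fold higher, percentile 77.7), and that gene was Chga, with 5 reads in S2 and 53 in S3 (9.94-fold higher, 4.0 to 31.9). Pdx1 had 5 reads in S2 and 1 in S3. Neat1 was 2.79-fold lower (2.73 to 2.85) and H19 11-fold higher (5.6 to 24.8).

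The fourth comparison, S3 over S0, sets the end of the protocol against its start. Most members of the plasma protein, cholesterol synthesis, NRF2 pathway and mesothelial lists were higher at the end, and most macrophage, interferon and cell cycle genes were lower. Alb was 15.3-fold higher (14.9 to 15.7), the glutathione transferase gene Gsta2 107-fold (78.6 to 149) and the decorin gene Dcn 17.5-fold (16.3 to 18.8). Csf1r was 38.0-fold lower (34.8 to 41.5), the platelet factor gene Pf4 740-fold (468 to 1250) and Mki67 7.1-fold (6.75 to 7.47). Malat1 was 1.81-fold higher (1.8 to 1.83), which did not pass the 2-fold rule. In total 1400 genes were higher and 1600 lower.

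Macrophage markers were lower for 24 of 26 members and higher for 0, with a median 25-fold lower (percentile 0.0). C1qc was 64.2-fold lower (54.9 to 75.6) and Cd74 222-fold (86.6 to 818). Interferon response genes had 14 of 26 members lower and 0 higher (median 3.62-fold lower, percentile 0.0), inflammation genes 9 of 23 lower and 5 higher (median 1.69-fold lower, percentile 0.0), and endothelial markers 7 of 18 lower and 2 higher (median 2.86-fold lower, percentile 0.0), the farthest being Stab1 (89.2-fold, 76.5 to 105), which macrophages also express. Of the PI3K-AKT genes 6 of 42 were lower and 1 higher (percentile 48.4). The 6 were again led by leukocyte genes, such as Inpp5d (47.9-fold, 39.1 to 59.3) and Pik3cg (38.8-fold, 29.0 to 53.2), and the 1 higher was Pik3r3, chosen after its values were seen. Pik3ca was 1.17-fold higher (1.12 to 1.23), Pik3r1 1.15-fold higher (1.1 to 1.21) and Akt1 1.22-fold lower (1.17 to 1.26), all within the 2-fold rule.

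Plasma protein genes were higher for 18 of 32 members and lower for 1 (median 3.4-fold higher, percentile 100.0), with Gc 20.3-fold higher (19.5 to 21.1) and F10, which macrophages also express, 32.8-fold lower (13.8 to 102). Of the 21 measured enzymes and transporters, 8 were higher and 1 lower (median 2.15-fold higher, percentile 100.0). Abcc2 was 23.4-fold higher (21.5 to 25.4) and Arg1 68.8-fold lower (45.7 to 109). The rest of the 42 listed genes stayed below 1 CPM at every stage. Liver transcription factors had 9 of 24 higher and 1 lower (median 2.04-fold higher, percentile 100.0), including Nr1h4 (6.55-fold, 5.13 to 8.45), whereas Hnf4a stayed within the rule (1.52-fold higher, 1.44 to 1.59). NRF2 pathway genes had 15 of 26 higher and 0 lower (median 2.87-fold higher, percentile 100.0), cholesterol synthesis genes 17 of 23 and 0 (median 3.38-fold higher, percentile 100.0) and fatty acid synthesis genes 8 of 19 and 1 (median 2.38-fold higher, percentile 100.0). Among the last were the desaturase genes Scd2 (16.0-fold, 15.4 to 16.5), Scd1 (14.2-fold, 13.1 to 15.5) and Fads2 (17.5-fold, 16.2 to 19). Retinoic acid response genes had 11 of 26 higher and 0 lower (median 2.25-fold higher, percentile 100.0).

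Mesothelial markers were higher for 7 of 11 members and lower for 1 (median 4.75-fold higher, percentile 100.0), with Gpm6a 44.0-fold higher (38.6 to 50.3), Upk3b 8.46-fold (7.82 to 9.17) and Wt1 6.18-fold (5.59 to 6.84). Fibroblast markers had 13 of 32 higher and 5 lower (median 1.85-fold higher, percentile 100.0), and the lower ones included the contractile genes Acta2 (11.5-fold, 11.2 to 11.7) and Tagln (5.52-fold, 5.4 to 5.65). Epithelial-mesenchymal transition genes had 9 of 25 lower and 1 higher (median 1.44-fold lower, percentile 0.0), with Vim 2.16-fold lower (2.14 to 2.19), and epithelial junction and keratin genes 10 of 24 higher and 1 lower (median 1.47-fold higher, percentile 99.7). The farthest higher gene of this comparison by the fixed rule was Cntn2 (939-fold, 586 to 1610), from 17 reads in S0 to 13998 in S3. Cell cycle genes stayed below S0 for 24 of 34 members with 0 higher (median 3.48-fold lower, percentile 0.0).

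At the end of the protocol, granule genes had 6 of 11 members higher and 0 lower (median at least 3.04-fold higher, percentile 99.9), including Vgf (17.8-fold, 14.2 to 22.6), Pcsk1n (at least 40.3-fold) and Chga (at least 20.1-fold, at 2.26 CPM). Beta cell genes had 3 of 15 higher and 1 lower (median 1.14-fold higher, percentile 68.4), with Slc2a2 8.39-fold higher (5.75 to 12.6) at 9.73 CPM. Pancreatic transcription factors had 2 of 11 higher, Pax6 (12.2-fold, 3.81 to 62.1) and Pou3f4, and 2 lower, among them St18 (median 1.78-fold higher, percentile 96.6). Their mean log2 ratio was -0.15 over the 10 members with a ratio, so mean and median differed in direction. Mafa had 4 reads in S0 and 15 in S3 (4.28-fold higher, 1.36 to 17.7), Neurod1 0 and 3, and Pdx1 6 and 1. Ins2 had its 1 read in S3, which lies at or under the floor, so no ratio can be given.

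**Figure D3:**
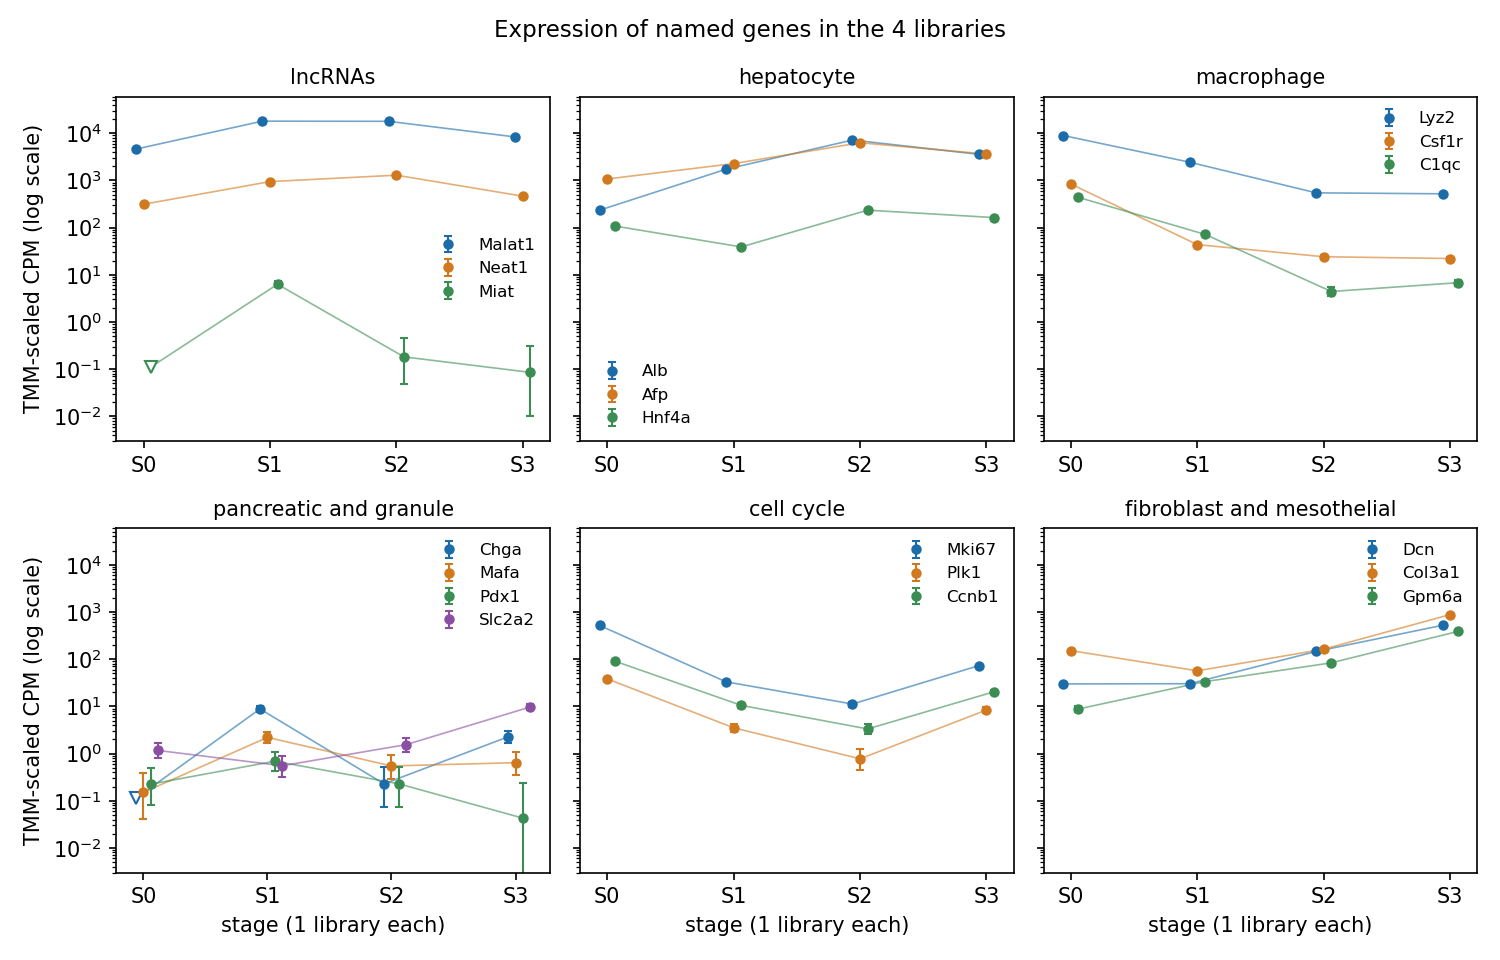
TMM-scaled CPM (y axis, log scale) of 19 named genes at stages S0 to S3 (x axis), 1 library per stage, with 95% counting intervals as bars and open triangles at the floor for 0 reads. Malat1 stands at 4602, 18013, 17866 and 8340 CPM, Mki67 at 518, 33.1, 11.2 and 73.0 CPM and Chga at 0, 8.82, 0.228 and 2.26 CPM. Lyz2 was chosen after its values were seen.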

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

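The 8 alternatives were fixed before the data were examined, and no recomputed value of a named gene counted as higher or lower, and no list median in the outer percentiles, changed direction under the 6 that could change it (other scaling, filter or RPKM). The 4-fold and point-estimate settings cannot turn a direction, and genes not named were not followed one by one. Other list medians near 0, such as that of the PI3K-AKT list, did change side with the scaling. The numbers of higher and lower genes stayed within 1.5 times the reported ones without TMM scaling, with DESeq2 size factors and with no filter. With a minimum of 10 CPM fewer genes were tested, and 903 genes were higher in S1 than S0, 725 lower in S2 than S1, 108 lower in S3 than S2 and 909 higher in S3 than S0. With a 4-fold limit, which is stricter by construction, higher and lower genes numbered 788 and 744 in S1 over S0, 179 and 531 in S2 over S1, 128 and 21 in S3 over S2, and 486 and 813 in S3 over S0. With the point estimate in place of the interval, which is looser by construction, they numbered 1684 and 2405 in S2 over S1 and 1240 and 686 in S3 over S2, and 2246 were higher in S3 than S0. With RPKM and a pseudocount of 1 they numbered 868 and 980, 401 and 541, 244 and 56, and 707 and 951 in the same order of comparisons. With a pseudocount of 0.1, 270 genes were lower in S3 than S2. For the RPKM settings the cause was not tested. Of 836 list medians under alternatives, 53 moved by 0.5 on the log2 scale or more, 34 of them with RPKM and a pseudocount of 1. Of 4257 values of named genes 1290 left their counting interval, 673 and 433 of them with RPKM at the larger and the smaller pseudocount, 154 without TMM and 30 with DESeq2. No paired analysis was possible because each stage has 1 library, and for the same reason no library could be left out in turn. Depth limits genes near the floor, such as Ins2, Pdx1 and Neurod1, for which differences were not detectable or have wide intervals.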

Other observations

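All 5 tests given here address patterns that had already been seen in these libraries. The lists of abundant neuronal transcripts and of REST targets were not among those fixed before the data were examined. The REST target list leaves out the genes farthest up, so its members depended on the ratios. The tests on loss of macrophages for Malat1 and on the share of hepatocyte-like cells were also chosen after the result was seen.

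Imprinted genes differed in both directions, with 7 of 31 higher and 5 lower in S1 over S0 (percentile 61.8) and 6 higher and 8 lower in S2 over S1 (percentile 5.5). Igf2, a fetal growth factor gene, was 3.49-fold lower in S2 than S1 and 13.3-fold higher in S3 than S2. Its neighbour H19 was 5.21-fold lower and then 11-fold higher. Growth factor receptor and feedback genes had 5 of 28 higher and 1 lower in S1 over S0 (percentile 73.2), with the receptor genes Kit 21.5-fold (8.97 to 67.5) and Erbb4 23.4-fold higher (9.75 to 73.2), and in S3 over S2, where the growth factors were left out, 3 higher and 1 lower (percentile 11.8), with Fgfr4 10.9-fold higher (5.31 to 26) and Dusp5 2.37-fold lower. Unfolded protein and integrated stress genes had 0 of 26 higher and 1 lower in S3 over S2 (percentile 0.2), which was Ddit3 (3.17-fold). Fatty acid oxidation genes had 4 of 22 higher and 0 lower in S3 over S0 (percentile 99), with the transporter gene Slc27a2, with 4 reads in S0, 11.1-fold higher (4.01 to 42.8).

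Mitochondrially encoded genes took 1.21%, 1.26%, 1.88% and 2.96% of the reads in S0 to S3, and 7 of 13 were higher and 0 lower in S3 over S0 (median 2.31-fold higher, percentile 100.0). Of 2 measured pancreatic acinar genes, Cela1 was 3.8-fold lower in S3 than S0 (2.0 to 7.82). Of 2 measured lymphocyte and erythroid genes, Cd79b, with 0 reads in S3, was at least 12.3-fold lower and Alas2 3.55-fold higher (2.64 to 4.84) in S3 than S0. The X-linked Xist stood at 69.7, 37.3, 49.0 and 34.7 CPM in S0 to S3 and the Y-linked Ddx3y at 120, 107, 163 and 184, Eif2s3y at 59.5, 75.8, 67.9 and 72.3, Kdm5d at 40.2, 19.1, 43.4 and 45.1 and Uty at 51.8, 23.6, 59.2 and 60.5 CPM. Uty was beyond 2-fold lower in S1 than S0 (2.2-fold), and Uty and Kdm5d beyond 2-fold higher in S2 than S1 (2.51-fold and 2.27-fold). Of the 1989 genes lower in S1 than S0, 1102 were also lower in S3 than S0 (55.4%), and of the 1915 higher in S1, 655 were also higher in S3 (34.2%). These comparisons share the S0 library, so the overlap has no baseline here.

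Neural and granule genes were higher in S1 than S0, and 10 of 14 neural markers and 5 of 11 granule genes were lower in S2 than S1. For members that reached 1 CPM in S1 alone, both directions were fixed by the filter. Of 39 targets of the neuronal repressor REST outside the fixed lists and the genes farthest up, 25 were measured and 16 of these were higher, with a median 7.65-fold higher (percentile 100.0), so loss of that repression is a candidate explanation, although 13 of the 25 already had at least 1 CPM in S0 and the targets are themselves neuronal genes. Neurons in the S1 culture stay open too, since 70.8% of measured abundant neuronal transcripts (17 of 24) were higher, between the 80% that neurons would need and the 60% set to exclude them. Of these 24, 15 had at least 1 CPM in S0, 8 are in the neural list and 4 in the REST list, and among those not higher, chosen after their values were seen, Camk2a had 43 reads in S0 and 9 in S1 and Basp1 was 2.12-fold lower. Both explanations, and a direct effect of the inhibitors of the S1 step, cannot be told apart with 1 library per stage.

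Malat1 was 3.91-fold higher in S1 than S0. A larger share of nuclear RNA in the S1 library is argued against by the sense intronic genes. Their median log2 ratio was -0.6 over 59 genes (quartiles -1.05 and 0.04, 1 gene higher) where at least 1 was predicted. However, the nuclear RNA Neat1 was 3.02-fold higher and the nuclear RNA Xist 1.87-fold lower. Xist was read beside Y-linked genes in every library, so its level may also follow the share of female cells, which was not tested. Loss of macrophages was set against fibroblast and epithelial markers, whose median log2 ratio was -0.02 over 56 genes (quartiles -0.78 and 0.98). The ratio of Malat1 was 1.97, above most of these markers whatever the scaling. Since this prediction was written after the result was seen, it cannot decide whether loss of macrophages was the whole cause. Loss of macrophages remains open, and the treatments of the S1 step remain open and untested with 1 library per stage.

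Hepatocyte plasma protein genes were higher in S3 than S0 while macrophage markers were lower. A larger share of the same hepatocyte-like cells would raise the list by about 1 factor, but 40.6% of its members (13 of 32) lay more than 1 log2 unit from the list median of 1.76, 7 above and 6 below. The limit set for excluding it was 40%, and without F10, which macrophages also express, the share was 38.7% (12 of 31), between that limit and the 20% below which it would be favoured. A change of share therefore stays open, as do the stage treatments, which 1 library per stage leaves untested.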
